A study of Caenorhabditis elegans with 2 samples.

How the data were processed

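EFL-1 is a transcription factor of the E2F family. It was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole Caenorhabditis elegans larvae of the first larval stage (L1). Per the labels, the worms were of strain YL418, in which an integrated transgene joins the ges-1 promoter, the efl-1 coding sequence with GFP and FLAG tags and the efl-1 3' untranslated region, beside an unc-119(+) rescue gene. The ges-1 promoter is active in the intestine, and in which tissues the tagged protein was present is not given in the sources used here. The labels describe the target as eGFP-tagged EFL-1 and name the antibody only as efl-1. Whether it binds GFP or EFL-1 itself is not given in the sources used here. The study holds 1 group of 2 biological replicates, numbered 2 and 3 in the labels, each with 1 technical replicate and a library size range of 150 to 350 bp.

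Per the file headers and notes deposited with each replicate, the files are narrowPeak lists on the genome builds ce10 and ce11. For each build there is a list of 30000 regions per replicate, a list of 30000 regions from both replicates pooled, and a set past an irreproducible discovery rate (IDR) threshold, derived by the authors from the replicate and pooled lists. The peak caller, the aligner and their versions are not given in the sources used here. Column 7 of the deposited lists holds a signal value for each region, whose scale differs between libraries. Column 9 holds the −log10 q-value the authors' caller gave, and 1741 of the ce11 IDR peaks share its highest value, so it was not used to rank peaks. Column 10, as deposited, gives the summit, the position of highest signal, as an offset from the region's start. The 1886 ce11 IDR peaks were the 1886 regions of highest signal in the pooled list. Read depth is unknown, because the lists hold no read counts, and no control track was used here. Per the notes deposited with the lists, each list was made from the replicate alignments and 1 further file. Whether that file is a control, and whether it corrects for the copy number of the transgene, is not given in the sources used here. Confidence intervals therefore cover counting of genes or peaks only.

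All comparisons used the ce11 lists with the matching WBcel235 genome and Ensembl annotation release 115. The ce10 lists entered only the counts of peaks and the replicate overlap, and no coordinates were converted between builds. A gene had a promoter peak if an IDR summit lay from 1000 bp upstream to 500 bp downstream of the 5' end of any of its transcripts. Of 19973 protein-coding genes on the 6 nuclear chromosomes, 2200 had one. A summit between divergent genes counted for both genes. The tests therefore treat as independent some genes that share a peak or an operon. The 12 gene lists were written before the data were examined, as were the comparisons, the tests and the rule for naming genes. Of the names written, 4 on the DNA replication list, 2 on the cohesion and repair list and 1 on the epidermis list matched no annotated symbol, and no gene stood on 2 lists. Each list was compared with all other protein-coding genes by a two-sided Fisher's exact test, adjusted over the 12 lists by the Benjamini-Hochberg method. Shares carry 95% Clopper-Pearson intervals.

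Motifs on either strand were sought within 100 bp of each summit and in a window of the same length centred 500 bp to the left. The shares were compared by an exact two-sided McNemar test. Each motif had its reversed, not complemented, sequence as a control of the same base composition. Differences of median signal and correlations were tested with 100000 permutations, two-sided, and the smallest p these can give is 1e-05. Replicates were compared by the share of the 1886 strongest regions of replicate 2 that met one of the 1886 strongest of replicate 3 by at least 1 bp, beside 100 circular shifts of 1 list. For single genes, the signal in each replicate was divided by that replicate's median over the IDR peaks and is given as mean ± SD (n = 2).

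The genes named are the 3 members of each list with the strongest promoter peak (2 for muscle, neurons, epidermis and pharynx), the genes at the 10 strongest peaks, and efl-1, ges-1 and unc-119, parts of which the transgene carries. Alternatives were the 943 strongest IDR peaks, the 1886 strongest regions of each replicate alone (leaving out the other replicate) or of the pooled list, and a window of 300 bp upstream to 100 bp downstream. Others were any part of a peak in the window, only genes without a same-strand gene ending within 500 bp upstream, motif windows of 50 or 250 bp, a right-hand flank, the consensus TTSSCGCS, 50% reciprocal overlap, 943 regions per replicate, ce10 lists and log2 signal.

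The functions were tested on simulated data. With summits placed at 80% of the promoters of 60 random genes, 40 of 40 simulated lists among 19973 genes were called, and 9 of 400 lists with nothing placed there were. With TTTGAA written into 30% of 1886 random windows, 20 of 20 runs were called, and 1 of 20 runs without it. A planted overlap of 70% came out as 70.3%. Among 200 unrelated data sets each, the correlation permutation called 6 and the median permutation 16. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.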

Results

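The data are lists of genome regions enriched in ChIP-seq described as against GFP-tagged EFL-1 in L1 larvae, in 1 group of 2 biological replicates without a second condition. The comparisons are therefore between EFL-1 peaks and gene annotation, between summits and their flanks, and between the replicates. The ce11 IDR set held 1886 peaks with a median width of 284 bp and signal values from 24.4 to 2581 (median 62.0). Read depth is unknown.

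EFL-1 peaks lay mostly at gene starts. The strongest one stood 295 bp upstream of the ribosomal protein gene rpl-3, and the next ones at the genes citk-2 and F59A6.11, at cdc-48.1, and at sec-61.G and F32D8.13. Of the 1886 summits, 1541 (81.7%, 95% interval 79.9 to 83.4%) fell in a promoter window of a protein-coding gene, while these windows cover 31.9% of the nuclear genome, a 2.56-fold excess. Windows of 300 bp upstream to 100 bp downstream held 60.7% of summits and cover 9.88% of the genome, a 6.14-fold excess. Among the 943 strongest peaks the share was 92.2%. Of the remaining summits, 197 lay between genes, 132 in introns, 13 in untranslated or non-coding exon sequence and 3 in coding exons. Summits outside promoter windows had a median signal of 38.4, against 73.7 inside.

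The 10 strongest peaks adjoined genes of several functions. The rpl-3 peak (WBGene00004414, chromosome III, 3867393 to 3867728, ce11) had a signal 36.9 ± 10.01 times the replicate's median (SD, n = 2). The peak between citk-2 and F59A6.11 (chromosome II, 4999180 to 4999516) reached 35.8 ± 1.02 times the median, and the cdc-48.1 peak (chromosome II, 10563429 to 10563738) 33.3 ± 3.38 times. Next came the peak at sec-61.G and F32D8.13 (28.2 ± 12.2), rpl-35 (29.2 ± 6.61), eelo-2 (23.7 ± 10.8) and the tubulin gene tba-2 (23.2 ± 6.98). The remaining ones were at dld-1 and nspg-9 (24.5 ± 0.480), rbd-1 and T23F6.3 (21.4 ± 5.16), and tasp-1 and K01G5.10 (20.1 ± 6.09). The summit counted for dld-1 and nspg-9 lay upstream of dld-1 and past the end of nspg-9. The replicate spreads of peaks next to each other in this order overlap, so the order of neighbours is not resolved. The spreads of rpl-3, citk-2 and cdc-48.1 lay above those of dld-1, rbd-1 and tasp-1, but spreads of 2 replicates are no test of order. Each lay within the 21 strongest regions of both replicates.

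Genes of DNA replication, mitosis, chromosome cohesion and repair, and the DREAM and synMuv chromatin group carried EFL-1 promoter peaks far more often than other genes. DREAM is the repressor complex that contains E2F, DP and retinoblastoma-like proteins, and synMuv genes act beside it in vulval development. The list was written more widely and also holds other chromatin genes, among them mes-2, mes-4, mrg-1 and zfp-1. The comparison asks whether EFL-1 sits at cell-cycle genes, the classical E2F targets. Peaks stood at mcm-2 to mcm-7, at orc-1, orc-3 and orc-5, and at rnr-1 and rnr-2, but not at orc-2, orc-4, rpa-1 or sld-5. These members were picked after their values were seen. Of 44 DNA replication genes, 36 had a peak (81.8%, 67.3 to 91.8%), against 10.9% of other genes (odds ratio 36.9, Fisher's exact test, adjusted p = 7.29e-27). Mitosis and cell cycle genes reached 50 of 65 (76.9%, odds ratio 27.5, Fisher's exact test, adjusted p = 1.77e-34). Cohesion and DNA repair genes reached 28 of 49 (57.1%, odds ratio 10.9, Fisher's exact test, adjusted p = 1.46e-14). For the DREAM and synMuv list the count was 22 of 37 (59.5%, odds ratio 11.96, Fisher's exact test, adjusted p = 3.29e-12). These calls held with either replicate left out.

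In the DNA replication list the strongest peaks belonged to the sliding clamp gene pcn-1, the origin recognition gene orc-5 and the topoisomerase gene top-2. The pcn-1 peak (WBGene00003955, chromosome IV, 4049556 to 4049848) was 248 bp upstream of the 5' end and 11.6 ± 5.16 times the median. The orc-5 peak (chromosome IV, 10734587 to 10734855) was 12.45 ± 1.22 times the median and is the same peak as that of the divergent cyclin gene cyb-1, 493 bp from its 5' end. The top-2 peak reached 10.3 ± 1.62 times the median. Among mitosis genes wee-1.3 led at 14.5 ± 0.0648, followed by the shared cyb-1 peak and kle-2 (11.3 ± 1.83). In cohesion and repair, the checkpoint genes hpr-17 (15.004 ± 3.74) and mrt-2 (8.63 ± 0.0134) and the polymerase gene polh-1 (12.7 ± 1.27) led. The polh-1 peak is the same peak as that of the ribosomal protein gene rps-22. In the DREAM and synMuv list efl-1 itself came first (21.9 ± 1.52), then mes-2 (14.5 ± 1.29) and lin-9 (7.37 ± 2.05). Peaks also stood at lin-35, dpl-1, lin-53 and lin-54, named here after their values were seen, and none at lin-37, lin-52 or efl-2. The lin-54 peak is the same peak as that of the ribosomal protein gene rpl-12.

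Ribosomal protein genes, among them rpl-3, rpl-35 and rpl-24.2, also carried EFL-1 peaks far more often than other genes. Of 82 genes, 67 had a promoter peak (81.7%, 71.6 to 89.4%, odds ratio 37.2, Fisher's exact test, adjusted p = 5.90e-49). With the window of 300 bp upstream to 100 bp downstream the count was 40 of 82 (48.8%), and 32 of 44 (72.7%) for DNA replication genes. The lists were not tested against each other. The strongest ribosomal peaks were at rpl-3, rpl-35 (chromosome III, 7854511 to 7854827) and rpl-24.2 (17.3 ± 4.06 times the median). The median signal over the 64 distinct peaks was 98.6, and 50 of them were among the 943 strongest. TTTGAA, the core of the cell cycle homology region element, lay at 39.1% of these peaks. In the flanks of all IDR peaks it lay at 43.7%, and at all IDR peaks of ranks 601 to 1000 at 42.25%. At the 943 strongest IDR peaks it lay at 61.0%.

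No list of germline, oocyte or tissue genes differed from other genes past the threshold. The labelled transgene is driven by the intestinal ges-1 promoter, and where the tagged protein was present is not given in the sources used here, so a low share cannot be read as absence of binding in the tissue where the genes are used. Germline and meiosis genes had peaks at the background rate, 6 of 54 (11.1%, odds ratio 1.01, Fisher's exact test, adjusted p = 1). The strongest were at cra-1 (3.44 ± 0.0985 times the median), coh-3 (2.26 ± 0.511) and spo-11 (1.90 ± 0.152, with the summit 942 bp upstream). Oocyte and maternal genes reached 8 of 44 (18.2%, odds ratio 1.80, Fisher's exact test, adjusted p = 0.171), led by par-2 (8.69 ± 2.14), cgh-1 (6.75 ± 1.07) and spn-4 (5.68 ± 0.359). With replicate 2 left out, that count was 10 of 44 (Fisher's exact test, adjusted p = 0.0364). The summits at par-2, cgh-1 and spn-4 lay 640, 796 and 402 bp upstream, and with a window of 300 bp upstream to 100 bp downstream no oocyte gene and 2 germline genes had a peak, shares below those of other genes. Intestine genes had peaks at 2 of 64, erm-1 (0.563 ± 0.0304) and ges-1 (0.482 ± 0.124), a share of 3.13% (odds ratio 0.260, Fisher's exact test, adjusted p = 0.0743). The intestine share passed the threshold with replicate 2 left out (1 of 64, Fisher's exact test, adjusted p = 0.0255). The other tissue lists stayed below the background without passing the threshold: muscle 1 of 40 (unc-45, 3.96 ± 0.441), neurons 2 of 57 (ric-19, 8.66 ± 0.309, and snb-1, 1.22 ± 0.190), epidermis and cuticle 1 of 51 (vab-10, 0.877 ± 0.156) and pharynx 1 of 30 (mlc-5, 0.901 ± 0.159). Their adjusted p-values by Fisher's exact test were 0.164, 0.129, 0.0743 and 0.270. Lists of this size cannot show a modest depletion from a background of 11.01%.

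**Figure D1:**
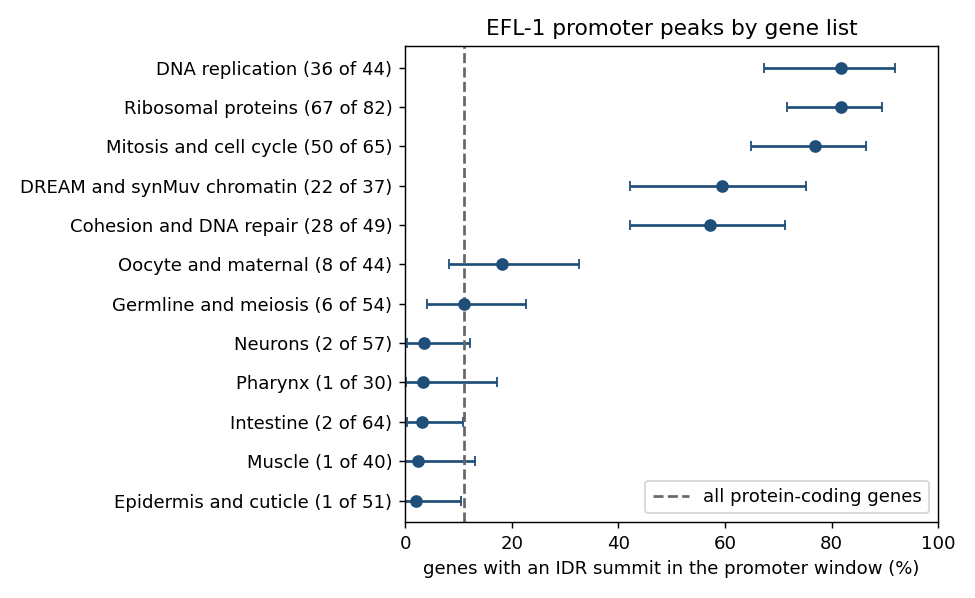
Share of each list's genes (%) with an IDR summit in the promoter window, with 95% Clopper-Pearson intervals and the number of genes. The dashed line is the share of all protein-coding genes, 11.01%, and 5 lists lie far above it, from 57.1% to 81.8%.

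The E2F consensus TTTSSCGC (S is C or G) and the TTTGAA element were both more frequent at EFL-1 summits than in the flanks, and the GATA consensus TGATAA was less frequent. The peaks of efl-1, pcn-1, wee-1.3, lin-9 and tba-2 each held the E2F consensus, and those of rpl-3, efl-1, pcn-1 and hpr-17 held TTTGAA. The E2F consensus lay at 234 of 1886 summits (12.4%, 10.95 to 13.98%) against 3.71% of flanks, an excess of 8.70 percentage points (exact McNemar test, p = 2.01e-23). Its reversed control rose too, from 1.22% to 6.20%, and the excess of the motif over that of the control was 3.71 points (95% interval 1.64 to 5.83). In relative terms the control rose more, 5.09-fold against 3.34-fold. Summit windows held 40.7% G or C and left flanks 37.3%. Peaks with the E2F consensus had a median signal of 110.0, and those without it 58.7 (permutation test, p = 1e-05, the smallest 100000 permutations can give).

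TTTGAA was more frequent at the strong EFL-1 peaks, such as those of rpl-3, citk-2, cdc-48.1 and efl-1, than at the weak ones. Of the 10 strongest peaks, 3 lacked it, those of dld-1, rbd-1 and tasp-1, and so did the peaks of orc-5 and top-2. Over all peaks it lay at 49.8% of summits and 43.7% of flanks (exact McNemar test, p = 0.000182), while its control AAGTTT fell from 27.6% to 21.2%. That excess of 6.15 points was 3.61 points with replicate 3 left out and 8.85 points with replicate 2 left out. At the 943 strongest peaks the share was 61.0% against 40.5% in flanks (exact McNemar test, p = 4.85e-19). At the 943 weakest, a split added after the data were seen, it was 38.7% against 46.9% (exact McNemar test, p = 0.000437). AAGTTT fell more at those weakest peaks, from 29.3% in flanks to 18.3% (exact McNemar test, p = 4.59e-08), so the deficit there is not particular to TTTGAA. TGATAA lay at 10.5% of summits and 17.4% of flanks (exact McNemar test, p = 1.41e-09), and its control AATAGT at 11.1% and 11.7%. The TGATAA difference was -6.89 points, and it was -4.29 with replicate 2 left out and -7.69 with replicate 3 left out. In windows of 250 bp on each side it was -2.12 points and no longer past the threshold (exact McNemar test, p = 0.185).

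**Figure D2:**
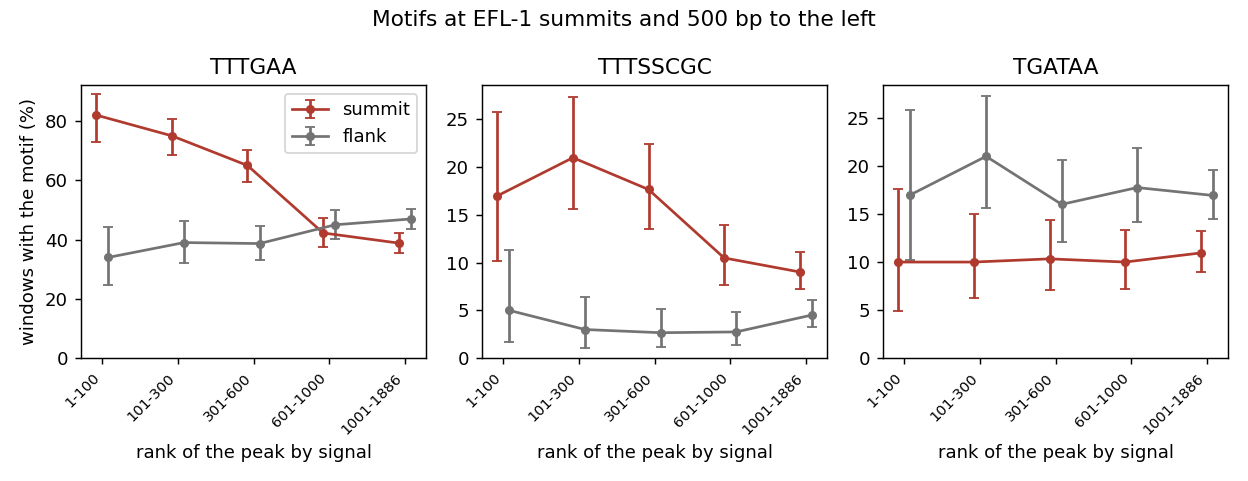
Share of windows (%) with TTTGAA, TTTSSCGC or TGATAA at summits and in left flanks, by rank of the peak's signal, with 95% Clopper-Pearson intervals. TTTGAA falls from 82.0% at the 100 strongest peaks to 38.8% from rank 1001 on, while TGATAA stays near 10% at every rank.

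EFL-1 peaks were rare at X-linked genes. Only 74 of 2731 X-linked genes had a promoter peak (2.71%, 2.13 to 3.39%), against 2126 of 17242 autosomal genes (12.3%, odds ratio 0.198, Fisher's exact test, p = 7.03e-66). The X share was 1.76% with replicate 2 left out and 0.366% among the 943 strongest peaks. Chromosome III, which holds rpl-3 and rpl-35, had 31.1 peaks per Mb, and X had 5.59. Within autosomes, 13.6% of genes in the middle 50% of the chromosome and 10.7% of genes in the outer parts had a peak (odds ratio 1.31, Fisher's exact test, p = 1.25e-08). Genes for tRNA had a peak at 63 of 612 (10.3%, 8.001 to 12.98%), close to the 11.01% of protein-coding genes (odds ratio 0.927, Fisher's exact test, p = 0.646). With replicate 2 left out, tRNA genes fell below protein-coding genes, with 37 of 612 (6.05%, Fisher's exact test, p = 0.00025).

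The loci that the transgene carries parts of, efl-1, ges-1 and unc-119, all had IDR peaks. The efl-1 promoter peak (WBGene00001161, chromosome V, 16965698 to 16965997) ranked 11 of 1886, with its summit 171 bp upstream of the 5' end and signals of 955 in replicate 2 and 442 in replicate 3. Its replicate summits were 8 bp apart, and the peak held both TTTGAA and the E2F consensus. At ges-1 a single weak peak lay 563 bp upstream (chromosome V, 1432558 to 1432841), ranking 1601, with signals of 26.1 and 7.58. The unc-119 gene (chromosome III, 10902641 to 10908935) held 4 IDR peaks with signals of 28.997, 48.7, 30.5 and 62.1. Reads from transgene copies cannot be separated from reads of the native ges-1 and unc-119 loci in peak lists.

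**Figure D3:**
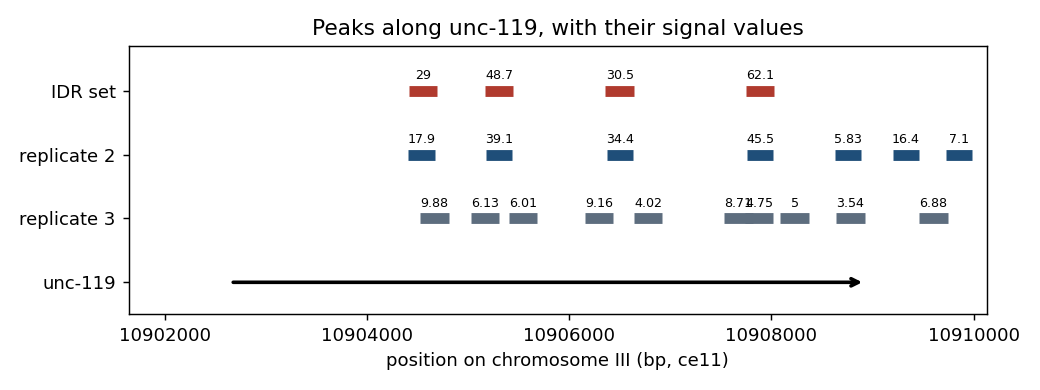
Map of unc-119 on chromosome III (bp, ce11) with the IDR peaks and the regions of each replicate list, labelled with their signal values. The 4 IDR peaks match regions of replicate 2 in position, while the regions of replicate 3 are mostly shifted. The signal values are not scaled between replicates.

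Both replicates placed EFL-1 at the same strong promoters. The signal of rpl-3 ranked 1 in replicate 2 and 3 in replicate 3, that of wee-1.3 ranked 53 and 29, and that of pcn-1 45 and 144. Of the 1886 strongest regions of replicate 2, 1359 (72.1%, 69.97 to 74.1%) met one of the 1886 strongest of replicate 3, against a mean of 1.08% and at most 1.75% under 100 shifts. Shifts move regions off promoter windows, which held 80.5% of the summits of these regions in replicate 2 and 77.6% in replicate 3. They are therefore a low bar for lists that both favour promoters. Replicate 2 had a counterpart for 1884 IDR peaks and replicate 3 for 1825. Across the 1823 peaks found in both, which are not independent replicates, Pearson's r was 0.947 and Spearman's rho 0.824 (permutation test, p = 1e-05 for each, the smallest possible). The IDR set holds the 1886 regions of highest pooled signal, and r and rho cover only those found in both replicates. Both values therefore describe that set and do not measure agreement at large. Of the IDR peaks, 1738 were among the 1886 strongest regions of replicate 2, and 1475 among those of replicate 3. Leaving out the 2 peaks farthest from the median of replicate 2 gave r = 0.947. Signals were a median of 2.48 times higher in replicate 2, so they are compared only after scaling to each replicate's median. Summits of the replicates lay a median of 11 bp apart at the 943 strongest peaks and 33 bp apart at the others.

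**Figure D4:**
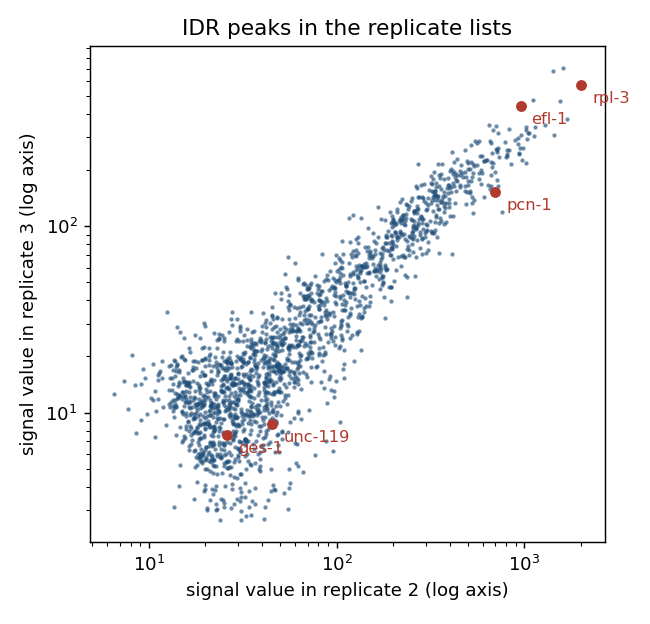
Signal value of each IDR peak in replicate 2 and in replicate 3 (log axes, 1823 peaks found in both lists), with 5 named genes in red. The peaks of rpl-3, efl-1 and pcn-1 lie at the strong end and that of ges-1 at the weak end, where the cloud of all peaks is broadest. The strongest unc-119 peak, of rank 942, lies at 0.994 times the median in replicate 2 and 0.453 times in replicate 3.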

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

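The weaker-peak split and the assignment of each peak to the nearest gene were chosen after the data were seen. Of 143 recomputed values, 126 kept their direction and side of the threshold, or stayed within their interval. The 5 lists above the background (DNA replication, mitosis, repair, DREAM and synMuv, ribosomal proteins) passed the threshold under every alternative run. The pooled-list alternative is identical to the IDR set by construction, tests nothing and is left out of these counts. With each replicate left out in turn, the intestine share ranged from 1.56 to 3.13%, the oocyte share from 18.2 to 22.7% and the tRNA share from 6.05 to 10.8%. Each passed the threshold without replicate 2 and not without replicate 3. Among the 943 strongest peaks the intestine share was 0% and the tRNA share 1.14%, both past it, and with the window of 300 bp upstream to 100 bp downstream the intestine share was 0%, past it too. That window also turned the direction against other genes, without passing the threshold, for the oocyte list (0%), the germline list (3.704%) and tRNA genes (8.66%, now above protein-coding genes). Giving each peak to the nearest gene did the same for the oocyte list (6.82%), the germline list (5.56%) and tRNA genes (8.17%), and any part of a peak in the window did so for the germline list (11.1%). The TTTGAA excess reversed to -8.17 points in the 943 weakest peaks, and the TGATAA deficit shrank to -2.12 points in windows of 250 bp on each side, no longer past the threshold. Replicate overlap moved to 59.9% with 50% reciprocal overlap and to 84.7% with 943 regions per replicate. The stricter overlap rule lowers the share by its construction, and for the other changes the cause was not tested. On ce10 the IDR set held 1962 peaks. Unknown read depth limits how far weak peaks, where the replicates differ most, can be read.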

Other observations

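Tests chosen only after the result was seen were those of unc-119, of the other orderings of TTTGAA, of the bases beside it, of gene families, of signal within the ribosomal list, of motifs and signal in each list against other promoter peaks, and of TTTSSCGC at mitosis genes against matched sets. The tests of the other patterns were written before their results were seen, on patterns noticed in the same data.

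The strong EFL-1 peaks, among them rpl-3, cdc-48.1 and efl-1, carried TTTGAA more often than the weak ones, by 22.3 percentage points (95% interval 17.9 to 26.7). In percentage points, the tables argue against base composition as the whole cause. The control AAGTTT differed by 25.7% of that amount (9.04 to 43.5%). None of the 59 other orderings of the same bases differed as much (median 0.742 points), the highest being the overlapping ATTTGA at 13.4 points. The interval of that ratio was computed after a stricter comparison, of the separate intervals of both differences (AAGTTT 2.01 to 9.44 points), had left the question undecided. Differences in points can be larger for common sequences, and AAGTTT was rarer, at 24.1% of the strong and 18.3% of the weak peaks. ATTTGA lay at 39.2% and 25.9%, and TTTGAA at 61.0% and 38.7%. Relative differences were not tested. Windows of the 943 strongest peaks held 39.7% G or C and those of the weakest 41.8%. For imprecise summits the answer is less clear. In windows of 250 bp on each side the weakest 943 peaks held fewer TTTGAA copies than their flanks. The excess over flanks was -33.2% of that in the strongest 943 (-62.0 to -8.43%). Within 100 bp of the weakest summits AAGTTT also fell, from 29.3% in flanks to 18.3%. The excess was not corrected for such a loss, so it cannot separate imprecise summits from a loss not particular to TTTGAA. The design holds no second condition, so no biological explanation was tested. What sets the weak peaks apart stays open.

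Ribosomal protein genes such as rpl-3, rpl-35 and rpl-24.2 often carried peaks. That only weak peaks make up the pattern is argued against by the median of 98.6 over their 64 peaks (95% interval 83.4 to 126), against 62.0 for all IDR peaks. Against other promoter peaks, with a median of 72.4, the difference of 26.2 did not pass the threshold (permutation test, p = 0.102 unadjusted and adjusted over 5 lists), so these peaks were not shown to be stronger. TTTGAA lay at 39.1% of these peaks (27.1 to 52.1%), an interval that holds the flank share of 43.7%, and TTTSSCGC at 4.69%. That flank share is of all IDR peaks, and the interval also holds the 49.8% of all IDR summits. At all IDR peaks of ranks 601 to 1000 the TTTGAA share was 42.25%, and the median rank of the ribosomal peaks was 691. Of the 64 peaks, however, 50 were among the 943 strongest, where TTTGAA lay at 61.0% of all IDR peaks. No set matched in rank was drawn for this list. Whether ribosomal peaks hold TTTGAA less often than ordinary ones of like strength was therefore not tested. Unspecific enrichment at strongly used promoters stays open. Within the list, the 25 peaks with TTTGAA had a median signal of 138, and the 39 without it 92.9. The permutation test gave p = 0.0363, unadjusted. On simulated unrelated sets that test called 16 of 200, so this difference is weak evidence. Whether rpl-3, rpl-35 and rpl-24.2, which hold the element, are like the rest stays open. No biological explanation was tested.

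The unc-119 gene held 4 IDR peaks, more than 99.9% of the 2751 protein-coding genes with any peak in the gene or within 1000 bp of it. Taking the strongest overlapping region of each replicate, its summits lay a median of 173.5 bp apart, farther than at 97.9% of IDR peaks. To the nearest summit of replicate 3 the median was 135 bp, and at 1 peak it was 14 bp. In this locus TTTGAA lay at 1 of the 4. Extra copies of unc-119 in the transgene may explain broad signal without a fixed summit. The labels place the efl-1 coding sequence in the same transgene, yet no IDR summit lay in the efl-1 gene body. Its 3 pooled regions had signals of 8.14 to 19.1, below the lowest IDR signal of 24.4 but above the pooled list's median of 7.83. The ges-1 promoter, also in the transgene, held a weak IDR peak with replicate summits 74 bp apart. The tables therefore leave the explanation open. Copy number was not measured here, whether the lists correct for it is not given in the sources used here, and no biological explanation was tested.

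At the TTTGAA nearest to each strong summit, bases 9 to 13 after its first base were often G or C. In the 943 strongest peaks these 5 positions held 52.9% G or C, against 40.7% at offsets 21 to 25 of the same 578 elements (exact sign test, p = 4.03e-09, higher in 304 and lower in 175 elements). In the 943 weakest peaks the values were 40.8% and 37.96% (exact sign test, p = 0.256), and in flanks 34.4% and 35.0% (exact sign test, p = 0.159). The difference between strong and weak peaks was not itself tested. A G or C rich block at a fixed distance from TTTGAA is a hypothesis from the same data, and no test addressed which protein might contact it.

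The E2F consensus TTTSSCGC lay at 19 of the 36 strongest peaks of DNA replication genes, among them pcn-1 and top-2, a share of 52.8%. Sets of other promoter peaks matched within 25 ranks of signal averaged 14.7% and reached at most 41.7% in 10000 draws, so signal strength does not account for it. Peaks of mitosis genes, among them wee-1.3, held it at 19 of 50, against a mean of 12.96% and at most 34% in their matched sets. Among 5 lists compared with other promoter peaks, the DREAM and synMuv list also passed for TTTSSCGC (31.8% against 12.1%, Fisher's exact test, adjusted p = 0.0224), and not for TTTGAA (59.1% against 52.3%, Fisher's exact test, adjusted p = 0.668). The ribosomal list lay below other promoter peaks without passing, for TTTSSCGC (4.69% against 12.7%, Fisher's exact test, adjusted p = 0.0669) and for TTTGAA (39.1% against 52.9%, Fisher's exact test, adjusted p = 0.0506). Peaks of cohesion and repair genes held it at 7 of 28, which missed the threshold against other promoter peaks (12.2%, Fisher's exact test, adjusted p = 0.0726 over 5 lists), and they carried TTTGAA at 82.1% against 51.8% (Fisher's exact test, adjusted p = 0.00858). Mitosis genes also passed for TTTGAA (70% against 51.8%, Fisher's exact test, adjusted p = 0.0343), and replication genes missed the threshold (69.4% against 51.96%, Fisher's exact test, adjusted p = 0.0534). The E2F consensus may thus mark cell-cycle promoters among EFL-1 targets, replication promoters included. Base composition was not matched, and lists were not tested against each other. The comparisons with other promoter peaks were not matched for signal either. Repair peaks had a median signal of 168 against 72.4 for other promoter peaks, and mitosis peaks 135 against 72.0. TTTGAA lay at 65% of all IDR peaks of ranks 301 to 600. How far signal strength accounts for the TTTGAA differences was not tested.

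Gene families with 10 or more numbered members, named here after their values were seen, differed widely in promoter peaks. Of 175 families, 47 passed the threshold by Fisher's exact test with Benjamini-Hochberg adjustment, 24 above and 23 below the other genes. Above it, nuclear pore genes (npp) had peaks at 19 of 26, translation initiation factors (eif) at 15 of 25, mitochondrial ribosomal genes (mrpl) at 18 of 41 and RNA polymerase subunits (rpb) at 7 of 11. Below it lay the chemoreceptor families str (0 of 193), srh (2 of 220) and srw (0 of 109), the C-type lectins (clec, 4 of 240), nuclear hormone receptors (nhr, 6 of 269) and collagens (col, 6 of 156). Among RNA genes, snoRNA genes had a peak at 94 of 346 (27.2%, 22.5 to 32.2%), not separated here from the genes that host them. The piRNA genes had one at 96 of 15363 (0.625%).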
